A study of Mus musculus with 4 samples.

How the data were processed

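The deposited intensity values were made with Agilent Feature Extraction 9.5.3.1, per the file headers and the submitters' processing notes. Per the labels' protocols, collagenase (1 mg/ml, with 10% serum) acted on the nodes for 30 minutes at 37 degrees, and 80 ng of total RNA per sample was amplified and coupled to a single dye. Per the file headers, the background was subtracted and a spatial and a multiplicative trend removed from each spot's intensity, and low spots received a surrogate value. The deposited files also hold other columns, flags of 0 or 1 for each spot that mark signals well above background, saturation and outliers. The headers place all 4 arrays on 1 slide scanned once, so no slide or scan effect could be estimated.

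A value table was deposited beside the scanner files. Its intensity values equal the mean processed signal of each probe times 1 factor per array (0.865, 0.862, 0.890 and 0.867 for pLN 1, mLN 1, pLN 2 and mLN 2), which set the 75th percentile to 1500, with values under 15 set to 15. This was found by comparing the deposited values with the scanner signals, and the labels do not state it. The column medians were 169, 172, 167 and 161, on a linear scale. It was used only in an alternative setting.

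From the processed signals, control spots and spots with an outlier flag were left out, the spots of a probe were averaged, log2 was taken and each array's 75th percentile was subtracted. Of 41174 probes, 19 lost all their spots on an array. A probe entered if it was well above background on both arrays of at least 1 node, which 31883 probes did. Each gene was represented by its entering probe with the highest mean, which left 21392 genes, 16906 of them with a current symbol. Probes were named from a table of RefSeq genes on GRCm38, used for names alone. The names of 24375 probes came from an accession, 6301 from a symbol and 2426 from a synonym, and 8072 kept the name in the files. Probe coordinates are those of the files, on mm8, and were not converted. Some transcripts are measured by probes that near-identical genes share, as for Ccl21a, which no probe names.

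Differences were tested with limma (lmFit and eBayes) on the 2 mLN against the 2 pLN arrays, without a block, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The prior had 2.35 degrees of freedom and the total was 4.35. Values after ± are standard errors, except for the stated purity, where they are standard deviations. Moderated p-values rest on the variance shared across genes, since an exact permutation of 2 against 2 arrays has 3 splits and cannot go below 0.333. The labels number the experiments, and the design text speaks of independent approaches, so the numbers mark a shared experiment of an mLN and a pLN sample. Across genes, the deviations of experiment 2 from experiment 1 in mLN and in pLN correlated with r = 0.246. The experiment was therefore also fitted as a block, and that result is given where it changed a call. Ratios within an experiment rest on 1 array per node and are given as values.

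Where a gene was not well above background on either array of a node, its fold is given as a bound, computed with that node's signal raised, where it lay below it, to the lowest log2 signal of any probe well above background on each array, and written as "at least". A gene named in the text whose probe was well above background on 1 of 2 arrays of the lower node got a limit in the same way, with the other array raised. Limits were also computed with 1 array left out, and are given where that moved them by over 1.5 times. A bound or limit takes the mean of the brighter node as measured, without its error, so smaller folds remain possible. For Areg the bound was 70.5-fold with pLN replicate 2 left out. Of the called genes, 42 were not well above background on either pLN array and 18 on neither mLN array. None of the called genes had a saturated probe.

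Gene lists were tested with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The same test with the correlation estimated from the data, and fry, a rotation test, were run beside it. The 42 lists held 823 genes, 809 of them named on the array and 775 tested. The sex-linked list kept 1 gene and was not tested as a list. With fry, 2 lists passed in a single direction, mesothelium and complement, and 23 passed when members were allowed to move either way. In 6 lists the median, the mean and the test differed in sign, and none of these passed. Genes past the threshold were also counted in each list with p-values adjusted over that list alone.

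The named genes, the lists, the tests and the alternatives were chosen before the data were examined, except where the text says otherwise. Named genes were the 10 largest positive and 10 largest negative log2 fold changes among genes that passed, had a symbol and had ratios of the same sign in both experiments. To these were added up to 4 members of each list with the smallest p, every called member of a list with up to 6 of them, and a fixed set of stromal and lipid genes. Some genes that this rule takes are not used here. Probes of cDNA clones, predicted genes and probes without a symbol were counted and not named, so 194 of the 225 called genes could be named.

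The procedure was tried on 10 simulated sets of 21392 genes, in each of which 200 genes changed. It called 0.4% of genes changed 2-fold, 56.2% of those changed 4-fold, 91.8% at 16-fold and 96.8% at 64-fold. Of 1285 genes called in all simulations, 59 were unchanged. No list was called when none had changed. Each simulated gene was drawn independently, so this does not test false calls of lists whose members vary together. Over the called lists, the correlation estimated from the data ran from −0.06 (complement) to 0.92 (pancreatic acinar cells), with 0.46 for mesothelium. A list of 15 genes shifted by 1 or by 5 (log2) was called in 10 of 10 simulations with the preset correlation and in 0 with the estimated one.

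Analyses were run in R 4.3.3 with limma 3.58.1, the packages data.table (version 1.17.8) and jsonlite (2.0.0).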

Results

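Gene expression was measured in CD45-negative cells from mouse lymph nodes, the cells left when leukocytes, which carry CD45, are removed. The design text calls them stem cells and the series title speaks of stromal cells. Cells from mesenteric lymph node (mLN), which drains the gut, were set against cells from peripheral lymph node (pLN) of wild-type C57BL/6NCrl mice. Tissue was digested with collagenase and the cells were isolated with magnetic beads, with a stated mean purity (± SD) of 97.4% ± 2.0 for mLN and 97.5% ± 2.2 for pLN. RNA of each node from 2 independent experiments was hybridised to 1-colour Agilent whole-genome arrays, which gave 4 arrays, 2 per node. A single dye was used and all arrays lay on 1 slide. The 75th percentile of the deposited signal ranged from 1686 to 1741, and 74.0% to 81.1% of 41174 probes were well above background on each array. The labels do not say whether the experiments used separate animals, so p-values measure the spread between these samples. Nor do they say which peripheral nodes were taken or how many animals made up a sample.

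The comparison asked which genes differ between the non-haematopoietic cells of the 2 nodes. Among the called genes higher in mLN were genes of mesothelium, the cell layer that covers the abdominal organs. Upk3b, a uroplakin made by mesothelium and urothelium, was 786-fold higher in mLN, a log2 fold change of 9.62 ± 0.15 (SE, n = 2 per node, limma adjusted p = 0.00265). Msln, which encodes mesothelin, was 470-fold higher (8.88 ± 0.57, adjusted p = 0.0159, and 8.14 to 9.62 with 1 array left out), and Slpi, the secretory leukocyte protease inhibitor, was 175-fold higher (7.45 ± 0.31, adjusted p = 0.00931). The retinaldehyde dehydrogenase gene Aldh1a2, whose product makes retinoic acid, was 78.8-fold higher (6.30 ± 0.29, adjusted p = 0.0108), and Nkx2-3, a homeobox gene of gut and spleen mesenchyme, was 64.1-fold higher (6.00 ± 0.26, adjusted p = 0.0101). In the other direction, Areg, which encodes the epidermal growth factor receptor ligand amphiregulin, was at least 103-fold lower in mLN (adjusted p = 0.0124), and Tbx15, a T-box gene of limb and trunk mesenchyme, was at least 87.4-fold lower (adjusted p = 0.00697), though 1 of its 3 entering probes gave −2.02.

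Of 21392 genes tested, 225 passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 166 of them higher and 59 lower in mLN. Their smallest fold was 2.51, and each of the 225 had ratios of the same sign in both experiments. The test favours genes whose arrays within a node lie close together, so the shared sign follows largely from the selection. At an unadjusted p below 0.05 there were 3140 genes. A rule without a test, a ratio of at least 2-fold the same way in both experiments, took 953 genes, 588 higher and 365 lower in mLN. The same rule applied to experiment 2 over experiment 1 in both nodes took 176 genes. Across genes the mLN over pLN ratios of the experiments correlated with r = 0.713, and genes are not independent replicates. The first principal component, with 69.2% of the variance, separated the nodes. No call held when either pLN array was left out, and fewer genes were called when either mLN array was, as given below. The residual spread then comes from the other node alone, so this does not show which arrays carry the differences. With 1 array left out none of the 225 changed sign, which again follows largely from the selection, and Upk3b had 9.54 to 9.70. In other settings signs did change, for 30 of the 225 with the planned normexp background and for 1 without a filter on dim probes. The count was 44 without a filter on dim probes, 354 with median scaling, 441 with an intensity trend in the variance, and 0, 358 or 582 with 3 forms of normexp background correction.

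**Figure D1:**
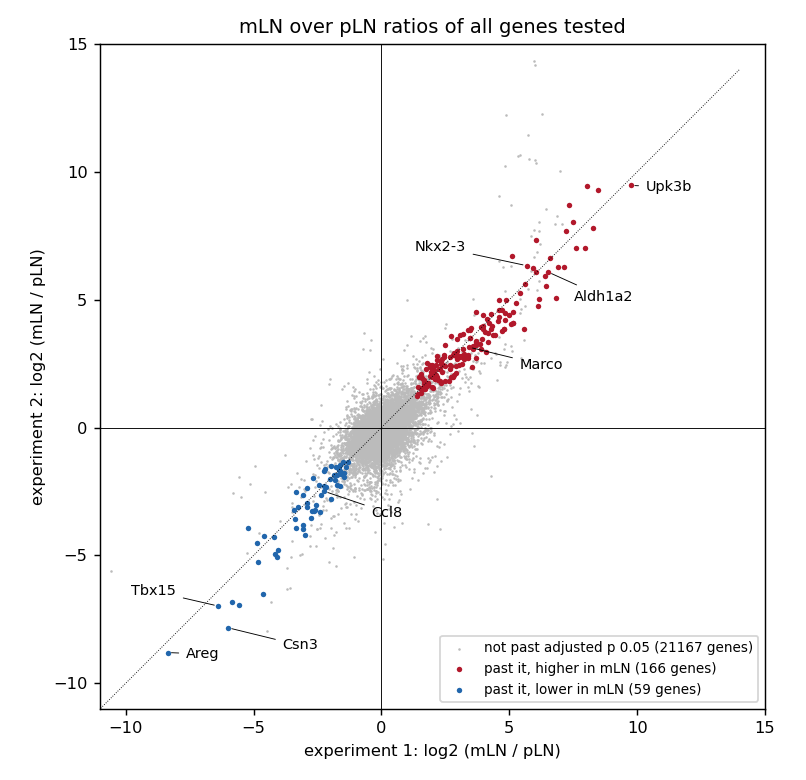
Log2 ratio of mLN over pLN in experiment 1 (horizontal axis) and experiment 2 (vertical axis), 1 point per gene tested, with the 166 genes called higher and the 59 called lower in mLN in colour, dim signals drawn as measured. The called genes lie near the dotted line of equal ratios, which follows largely from the test that selected them, with Upk3b at 9.77 and 9.47. Grey points far above the line near a horizontal value of 6 had ratios that differed between the experiments.

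Ranked by fitted value, the 10 named genes with the largest positive fold changes were completed by Upk1b, Bnc1, Lrrn4, Wt1, Amy2a5, Svs5 and Myl7. Upk1b, a second uroplakin gene, and Lrrn4 were well above background on 1 pLN array only, and were at least 309-fold and 238-fold higher in mLN (adjusted p = 0.0201 and 0.0179, and limits of 148-fold to 383-fold for Lrrn4 with 1 array left out). Bnc1 and the Wilms tumour gene Wt1, transcription factors made by mesothelium, were not well above background on either pLN array, so only bounds hold for them. Bnc1 was at least 62.5-fold higher in mLN (adjusted p = 0.00486) and Wt1 at least 72.8-fold (adjusted p = 0.0089). The same was true of Amy2a5, a pancreatic amylase (at least 53.2-fold, adjusted p = 0.034, with limits of 28.3-fold to 99.8-fold when 1 array was left out and 3.52-fold by its other probe), and of Svs5, a seminal vesicle protein gene (at least 67.0-fold, adjusted p = 0.00697). Myl7, which encodes an atrial myosin light chain, was 105-fold higher (6.71 ± 0.31, adjusted p = 0.0108). Leaving out either mLN array ended the calls of Lrrn4 (values 7.90 and 8.15) and Upk1b (8.54 and 8.97). Leaving out either pLN array ended every call, for these genes and for those named below.

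The 10 named genes with the largest negative fitted values also held Csn3, Shox2, Cxcl15, Arg2, Cyp2f2, Olfr1046, Wfdc2 and Mlana. Csn3, which encodes kappa-casein, was 120-fold lower in mLN (−6.91 ± 0.57, adjusted p = 0.0252, and −7.72 to −6.10 with 1 array left out), and Wfdc2, a whey acidic protein domain gene of glandular epithelium, was 23.6-fold lower (−4.56 ± 0.28, adjusted p = 0.0155). Shox2, a homeobox gene of the developing limb, was at least 31.7-fold lower (adjusted p = 0.0159) and Arg2, the mitochondrial arginase, at least 20-fold lower (adjusted p = 0.0391). The chemokine gene Cxcl15 was well above background on 1 mLN array only and was at least 36.8-fold lower (adjusted p = 0.0425, and at least 5.10-fold by its other probe). Cyp2f2, a cytochrome P450 of airway epithelium, was 33.3-fold lower (−5.06 ± 0.37, adjusted p = 0.0188), and Mlana, a melanocyte antigen gene, was 23.6-fold lower (−4.56 ± 0.39, adjusted p = 0.0287). The olfactory receptor gene Olfr1046 was at least 4.99-fold lower (adjusted p = 0.0197), a bound of −2.32 on the log2 scale. With normexp on a single background per array its value was smaller in size than that (−1.22), and the planned normexp background turned it to 0.68. With an mLN array left out, the calls of Csn3 (either array, adjusted p 0.0713 and 0.0719), Cyp2f2 (mLN replicate 1, 0.0594) and Olfr1046 (mLN replicate 1, 0.0571) ended. That of Olfr1046 also ended with the deposited value table (adjusted p = 0.065) and with normexp on a single background per array (0.0552), and that of Tbx15 (value −2.02, adjusted p = 0.0628) among probes well above background on all 4 arrays.

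Probe positions are given in the mm8 assembly, as the files state them. The Upk3b probe lies on chromosome 5 from 136329279 to 136329338, the Aldh1a2 probe on chromosome 9 from 71094684 to 71094743 and the Nkx2-3 probe on chromosome 19 from 43668520 to 43668578. The Areg probe lies on chromosome 5 from 92216264 to 92216323 and the Tbx15 probe on chromosome 3 from 99482760 to 99482819. Among the 225 called genes, 55 had several entering probes, and in 2 of these the probes differed in sign.

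**Figure D2:**
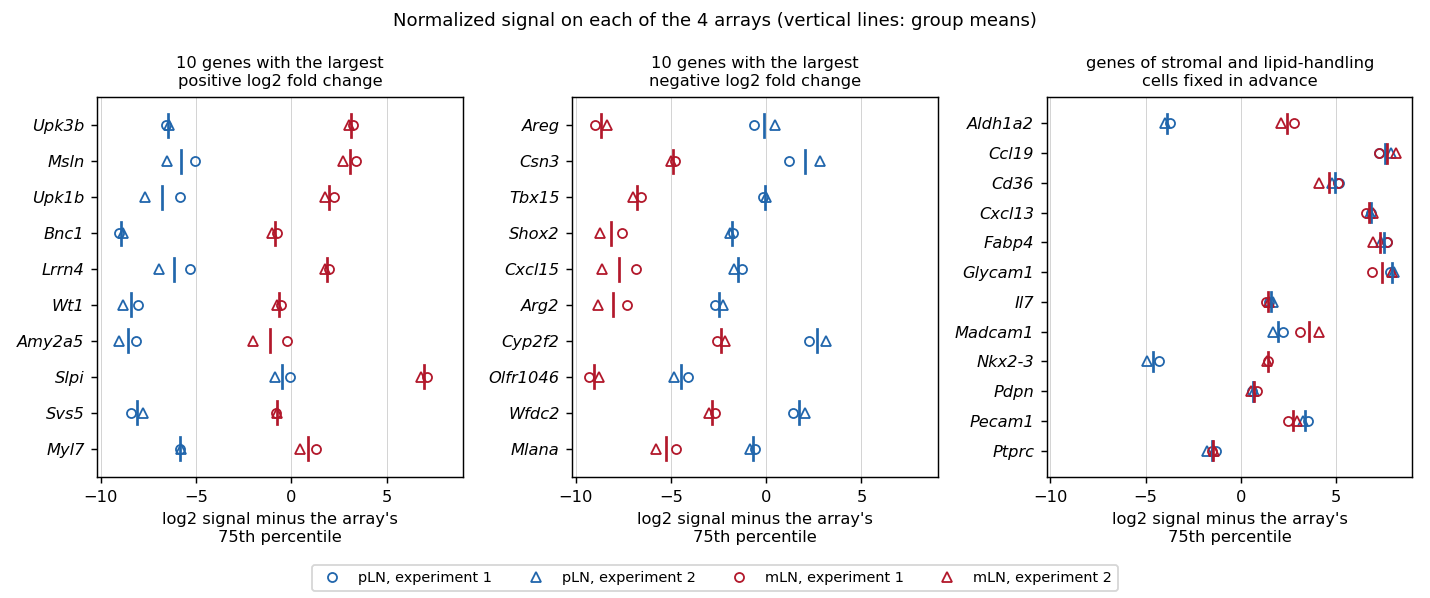
Log2 signal minus the array's 75th percentile (horizontal axis) of named genes (vertical axis) on each of the 4 arrays, circles for experiment 1, triangles for experiment 2, blue for pLN, red for mLN, with a vertical line at each group mean. The nodes are apart in every gene of the left and middle panels, and in the right panel the values of Aldh1a2 and Nkx2-3 are apart while Pdpn, Cxcl13 and Ptprc overlap.

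Of the stromal and lipid genes chosen before the data were examined, the stromal chemokines had fold changes of 0.12 ± 0.39 (log2) for Ccl19 and −0.06 ± 0.19 for Cxcl13, and the T cell survival factor Il7 had −0.17 ± 0.16 (−0.28 to −0.06 with 1 array left out). The values were 0.03 ± 0.17 for Pdpn, which encodes podoplanin, and 0.06 ± 0.21 for Ptprc, which encodes CD45 itself. None of these passed, with adjusted p from 0.73 to 0.968, and since 0.4% of simulated 2-fold changes were called, these values do not show equal levels. Madcam1, the addressin that guides lymphocytes to gut tissue, had 1.64 ± 0.41 (adjusted p = 0.191), and Glycam1, a mucin of high endothelial venules, had −0.55 ± 0.39 (adjusted p = 0.623, and −1.08 to −0.02 with 1 array left out). The fatty acid transporter Cd36 had −0.35 ± 0.37 and the fatty acid binding protein Fabp4 −0.24 ± 0.30 (adjusted p = 0.76 and 0.802). The signs of Ccl19, Cxcl13, Pdpn, Ptprc, Cd36 and Fabp4 each turned in at least 1 alternative setting. Ccl21a could not be followed, because the only such probe is named for its near-identical copy Ccl21c.

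Genes were also read as 42 lists fixed before the data were examined, 41 of which had enough members to be tested against all other genes with camera at a preset correlation of 0.01. The test called 17 lists, 12 higher and 5 lower in mLN. Its p-values can be too small where members vary together by more than the preset value. Examples are pancreatic genes (estimated correlation 0.92) and interferon-stimulated genes (0.70). The rotation test fry passed 2 lists in a single direction, mesothelium and complement. With the correlation estimated from the data no list passed, the lowest adjusted p being 0.657, and in 10 simulations of 4 arrays a list of 15 genes shifted by 5 on the log2 scale did not pass that form either, so it could not separate lists here. For each list called below, that second adjusted p is given with it. Where leaving out 1 array moved a median by over 1.5 times, a range over the 4 arrays left out follows it, except for lists that did not pass and turned sign, whose ranges stand with the other alternatives.

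Of 7 lists of tissues that can adjoin a node, mesothelium, pancreatic acinar cells and surface and glandular epithelium passed and 4 did not. Of 15 mesothelium genes tested, 11 were called higher in mLN and none lower, and 12 passed when adjusted over the list alone. Their median log2 fold change was 2.81, also with 2 of them at their bounds (camera adjusted p = 3.49e-17, and adjusted p = 0.657 with an estimated correlation). Efna5, an ephrin ligand gene among them, had 2.81 ± 0.16 (adjusted p = 0.014), with its 2 probes at 0.13 and 2.81 and their mean at 1.47. All 17 pancreatic acinar genes, which encode digestive enzymes and their cofactors, were at least 2-fold higher in mLN in both experiments, with a median of 7.98 (range 5.16 to 10.92, camera adjusted p = 7.99e-13, and adjusted p = 0.657 with an estimated correlation). None passed over all genes, and 16 passed when adjusted over the list alone. Cel and Cpa1 had 5.73 ± 0.71 and 7.56 ± 1.38 (4.84 to 6.62 and 5.82 to 9.31 with 1 array left out), and Pnliprp2, well above background on 1 pLN array only, had a bound of 78.2-fold, or 41.0-fold to 149-fold with 1 array left out (adjusted p 0.0624 to 0.122, and 0.015 to 0.0187 with the experiment as a block). Pancreatic signal also differed between experiments within a node. The median of the 17 genes lay 1.04 above the 75th percentile on pLN replicate 1 and at −5.23 on pLN replicate 2, and at 6.56 and 5.12 on the mLN arrays.

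Surface and glandular epithelium genes were lower in mLN, with a median of −1.80 over 16 genes (range −2.44 to −1.09, −1.73 with 2 of them at their bounds, and −0.13 with the planned normexp background) and 12 of them negative in both experiments (camera adjusted p = 5.83e-08, and adjusted p = 0.657 with an estimated correlation). The 3 called members were Csn3, Wfdc2 and Esrp1, a splicing regulator of epithelial cells (at least 3.21-fold lower, adjusted p = 0.0208), and 7 passed when adjusted over the list alone. Elf5, a luminal epithelial transcription factor gene, was not well above background on either mLN array and did not pass over all genes (a bound of 18.4-fold, or 10.3-fold to 33.0-fold with 1 array left out, adjusted p = 0.0764, and 0.0499 with the experiment as a block). The call of Esrp1 ended with either mLN array left out (values −3.30 and −2.99). It also ended with the deposited value table (−1.53, adjusted p = 0.0717) and with normexp on a single background per array (−0.73, 0.0863). These last values are smaller in size than the bound (−1.68 on the log2 scale), and the planned normexp background turned Esrp1 to 1.17. The intestinal epithelium list did not pass (median 0.17 over 13 genes, adjusted p = 0.462). Neither did skeletal muscle (median 0.00 over 15 genes, range 0.01 to 0.06, adjusted p = 0.974), adipocytes (median −0.17 over 14 genes, 0.974) or Schwann cells and nerve (median −0.01 over 14 genes, 0.408). In the nerve list Gfra3, a neurotrophic factor receptor gene, was called (1.38 ± 0.15, adjusted p = 0.0497, and 0.0557 with the experiment as a block), a call that also ended with either mLN array left out (0.0959 and 0.0806) and with the mean of probes (0.0522). Among adipocyte genes, Plin1 had 1.82 ± 0.49 and Cidea −3.76 ± 1.23 (adjusted p = 0.212 and 0.289, and 1.15 to 2.49 and −5.57 to −1.95 with 1 array left out).

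**Figure D3:**
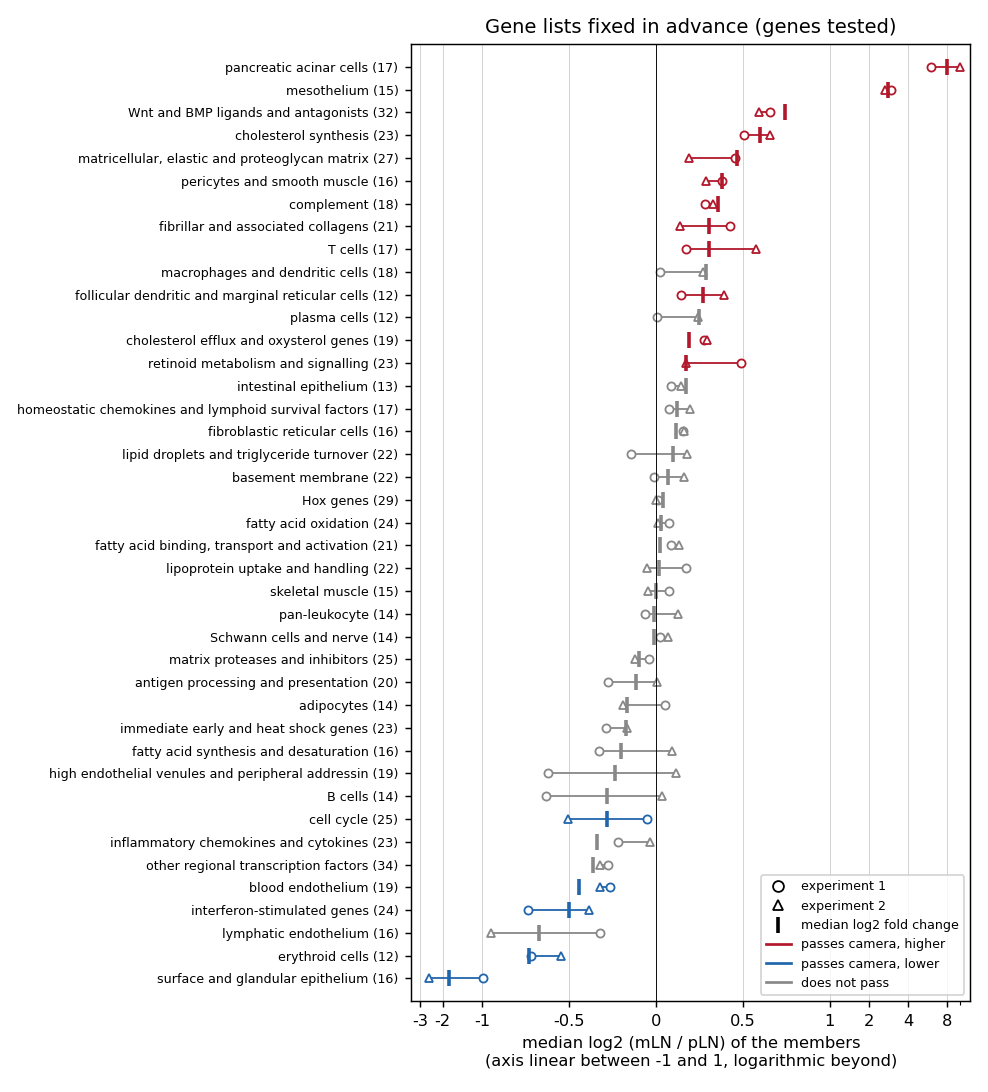
Median log2 ratio of mLN over pLN of the members of 41 gene lists (vertical axis, number of genes tested in parentheses) in experiment 1 (circles) and experiment 2 (triangles), with a bar at the median log2 fold change. The horizontal axis is linear between −1 and 1 and logarithmic beyond. Pancreatic acinar genes (5.96 and 10.02) and mesothelium (2.96 and 2.67) lie furthest to the right and surface and glandular epithelium (−0.99 and −2.56) furthest to the left.

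Transcription factors of body position went both ways. In a list of 34 regional factors other than Hox genes, 4 were called higher and 4 lower in mLN, and 17 passed when adjusted over the list alone, 6 higher and 11 lower. Isl1, a homeobox gene of foregut and heart mesoderm, was at least 35.9-fold higher in mLN (adjusted p = 0.00697), beside Wt1 and Nkx2-3. Tbx15 and Shox2 were among the 4 lower. The list as a whole did not pass (median −0.36, range −0.43 to −0.21, camera adjusted p = 0.1). None of 29 Hox genes was called (median 0.04, camera adjusted p = 0.839). The 2 with the smallest p had opposite signs, Hoxd8 at −1.03 ± 0.17 and Hoxc6 at 0.74 ± 0.15 (adjusted p = 0.108 and 0.138).

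Ligands and antagonists of the Wnt and BMP pathways were higher in mLN as a list, with a median of 0.74 over 32 genes (camera adjusted p = 2.41e-05, and adjusted p = 0.657 with an estimated correlation). The called members were Wnt2b (3.39 ± 0.23, adjusted p = 0.0161), Rspo3 (2.46 ± 0.14, adjusted p = 0.0155) and Rspo1 (2.45 ± 0.23, adjusted p = 0.0337), a Wnt ligand and 2 R-spondins, which enhance Wnt signalling. Rspo1 was also a member of the mesothelium list. Adjusted over the list alone, 16 genes passed higher and 3 lower. With the experiment as a block, Rspo1 did not pass (0.051), nor without either mLN array (0.0675 and 0.0522), nor did Rspo3 as the mean of its probes (0.0554). Wnt5a missed the threshold (1.41 ± 0.16, adjusted p = 0.0512).

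Retinoid genes passed as a list (camera adjusted p = 0.0283, and adjusted p = 0.657 with an estimated correlation) although their median was 0.18 over 23 genes (range 0.26 to 0.55, and 0.73 among probes well above background on all 4 arrays). The called members were Aldh1a2 and Lrat, which encodes the enzyme that esterifies retinol for storage (4.09 ± 0.36, adjusted p = 0.03), and 8 genes higher and 2 lower passed when adjusted over the list alone. Crabp2, a retinoic acid binding protein gene, was not well above background on either mLN array (adjusted p = 0.111). The list did not pass with mLN replicate 1 left out (adjusted p = 0.151).

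Lipid handling, the subject of the series title, was read through 7 lists. Genes of cholesterol synthesis passed with a median of 0.60 over 23 genes (range 0.39 to 0.71), 20 of them positive in both experiments (camera adjusted p = 1.14e-08, and adjusted p = 0.657 with an estimated correlation). None passed over all genes, and 2 passed when adjusted over the list alone, among them the sterol reductase gene Tm7sf2 (0.93 ± 0.17). Genes of cholesterol efflux and oxysterols passed with a median of 0.19 over 19 genes (range 0.19 to 0.34, camera adjusted p = 0.00658, and adjusted p = 0.657 with an estimated correlation). Of them Star, which encodes the protein that carries cholesterol into mitochondria, was higher in mLN (3.05 ± 0.16, adjusted p = 0.0123), and the exporter gene Abcg1 was lower (−1.69 ± 0.18, adjusted p = 0.0453, and 0.0588 with the experiment as a block). The sterol hydroxylase genes Cyp7b1 (1.15 ± 0.15) and Cyp27a1 (1.03 ± 0.14), had adjusted p values of 0.0666 and 0.0772. The efflux list did not pass with mLN replicate 2 left out (0.0588), and the call of Abcg1 also ended with either mLN array left out (0.0857 and 0.103).

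The other 5 lipid lists did not pass and held no called gene. Their medians were 0.02 over 22 genes for lipoprotein uptake (camera adjusted p = 0.4), 0.03 over 21 genes for fatty acid binding, transport and activation (range 0.02 to 0.06, adjusted p = 0.462), 0.10 over 22 genes for lipid droplets and triglyceride turnover (0.261), −0.20 over 16 genes for fatty acid synthesis and desaturation (0.839) and 0.03 over 24 genes for fatty acid oxidation (0.417). Their members with the smallest p went both ways. They were, in the same order, Scarb1, the high-density lipoprotein receptor (−0.95 ± 0.19, adjusted p = 0.135), Slc27a2, a fatty acid transporter not well above background on either mLN array (adjusted p = 0.134), the acyltransferase gene Gpam (1.00 ± 0.27, adjusted p = 0.208), the desaturase gene Fads2 (0.55 ± 0.17, adjusted p = 0.268) and the thiolase gene Acaa2 (0.78 ± 0.23, adjusted p = 0.244).

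**Figure D4:**
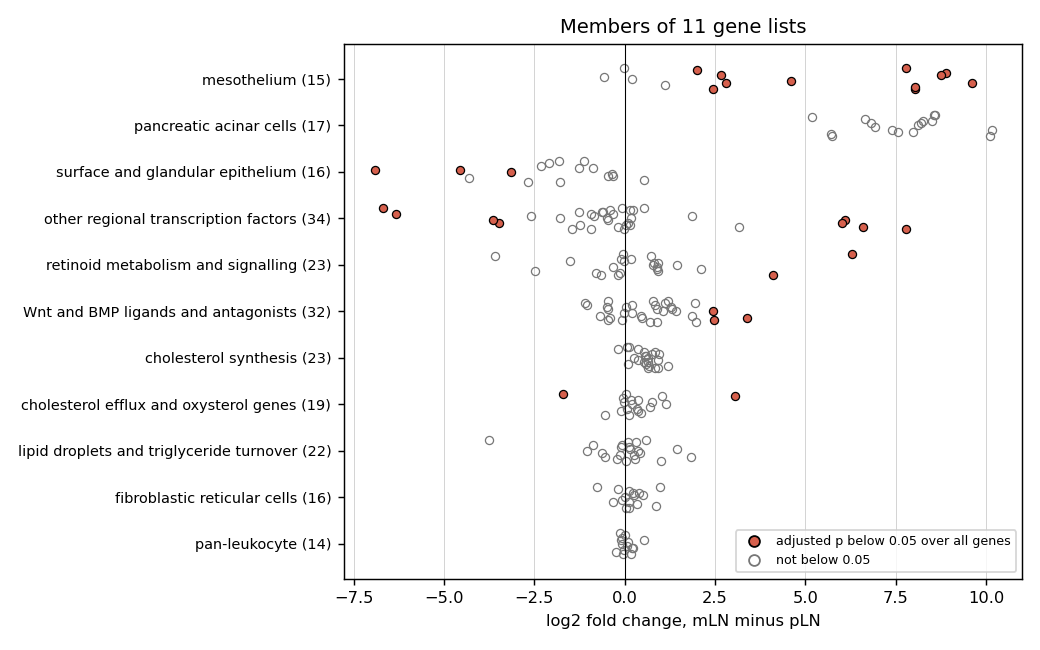
Log2 fold change of mLN over pLN (horizontal axis) of each member of 11 gene lists (vertical axis, number of genes tested in parentheses), filled where the adjusted p over all genes was below 0.05. Mesothelium holds 11 filled points on the right, regional transcription factors 4 on each side, and the pancreatic genes all lie far to the right with none filled.

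Among stromal cell types, the fibroblastic reticular cell list did not pass (median 0.12 over 16 genes, range 0.02 to 0.18, camera adjusted p = 0.0735). With the planned normexp background it passed with a turned median (−0.14, camera adjusted p = 0.0293). Its members Lum and Dpt, which encode matrix proteins, had 0.86 ± 0.14 and 0.98 ± 0.18. In the reported setting both passed only when adjusted over the list alone, and each passed over all genes in 2 of 15 alternative settings. Blood endothelium was lower in mLN, with a median of −0.44 over 19 genes (range −0.44 to −0.24), 13 of them negative in both experiments and none called (camera adjusted p = 0.0048, and adjusted p = 0.657 with an estimated correlation). Sox18, Emcn and Pecam1, endothelial genes of that list, had −0.64 ± 0.14, −0.54 ± 0.14 and −0.67 ± 0.22 (Pecam1 −0.91 to −0.43 with 1 array left out). Lymphatic endothelium did not pass (median −0.67 over 16 genes, range −0.94 to −0.25, camera adjusted p = 0.0702, and 0.0219 with the experiment as a block). It passed in 10 of 15 alternative settings, and its median was negative in all of them. Of its genes 13 were negative and 3 positive, none called. The hyaluronan receptor gene Lyve1, at 1.04 ± 0.17 (adjusted p = 0.105), was among the 3. High endothelial venules did not pass either (median −0.23 over 19 genes, adjusted p = 0.697), but held the called interleukin receptor gene Il18r1 (2.98 ± 0.21, adjusted p = 0.0179). Pericytes and smooth muscle passed with a median of 0.38 over 16 genes (camera adjusted p = 0.00725, and adjusted p = 0.657 with an estimated correlation), with Acta2 at 0.59 ± 0.16 and Tagln at 0.70 ± 0.19. Follicular dendritic and marginal reticular cells passed with a median of 0.27 over 12 genes (0.0388, and adjusted p = 0.735 with an estimated correlation). Their named members went both ways, Mfge8 at 0.83 ± 0.18, Cr2 at 1.30 ± 0.31 and Coch at −1.37 ± 0.30, none called. That last list did not pass with quantile scaling (0.0623), median scaling (0.0502) or the second array of either node left out (0.169 and 0.302), nor did blood endothelium without mLN replicate 2 (0.0538).

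Of 4 matrix lists, 2 passed. Matricellular, elastic and proteoglycan genes had a median of 0.47 over 27 genes (range 0.15 to 0.62, camera adjusted p = 0.00321, and adjusted p = 0.735 with an estimated correlation), with Cilp, a cartilage matrix protein gene, at 1.32 ± 0.16 (adjusted p = 0.0564). Collagens had a median of 0.31 over 21 genes (range 0.01 to 0.48, adjusted p = 0.00658, and adjusted p = 0.736 with an estimated correlation). Col14a1, which encodes a fibril-associated collagen, was their called member (1.79 ± 0.19, adjusted p = 0.0468), but its 2 probes lay at −0.43 and 1.79 and their mean did not pass (0.68, adjusted p = 0.41). Nor did it pass with either mLN array left out (0.0855 and 0.0694) or with quantile scaling (0.051). Without mLN replicate 1 neither list passed (0.18 and 0.387), and the collagens did not pass without pLN replicate 2 (0.106). Basement membrane (median 0.07 over 22 genes, adjusted p = 0.537) and matrix proteases (median −0.10 over 25 genes, range −0.16 to −0.05, adjusted p = 0.653) did not pass. Among proteases, Mmp3, the stromelysin, had −1.47 ± 0.18 (adjusted p = 0.0602).

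Of the immune mediators, interferon-stimulated genes were lower in mLN, with a median of −0.50 over 24 genes (range −0.59 to −0.28), 19 of them negative in both experiments and none called (camera adjusted p = 2.03e-05, and adjusted p = 0.735 with an estimated correlation). Ifit2 and Isg15 had −0.99 ± 0.24 and −0.66 ± 0.16. Complement genes were higher as a list, with a median of 0.36 over 18 genes (range 0.22 to 0.43, adjusted p = 0.00881, and adjusted p = 0.657 with an estimated correlation), with C3 at 0.65 ± 0.17. Inflammatory chemokines and cytokines (median −0.34 over 23 genes, 0.105), homeostatic chemokines and survival factors (median 0.12 over 17 genes, 0.261) and antigen presentation (median −0.12 over 20 genes, 0.261) did not pass. Ccl8, a monocyte-attracting chemokine gene, was lower in mLN (−2.36 ± 0.17, adjusted p = 0.0185), and the chemokine gene Cxcl14 was higher (2.91 ± 0.21, adjusted p = 0.019).

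Markers of leukocytes, which the isolation was meant to remove, were read in the same way. The pan-leukocyte list had a median of −0.01 over 14 genes (adjusted p = 0.544), and B cells (median −0.28 over 14 genes, range −0.48 to −0.12, adjusted p = 0.105) and plasma cells (median 0.25 over 12 genes, range 0.13 to 0.25, adjusted p = 0.0735) did not pass. Jchain, which joins secreted antibodies, had 2.37 ± 0.27 (adjusted p = 0.053, and 0.0315 with the experiment as a block). T cell genes passed with a median of 0.30 over 17 genes (range 0.07 to 0.48, adjusted p = 0.0152, and adjusted p = 0.735 with an estimated correlation), with Cd8a at 1.11 ± 0.18, but not with mLN replicate 2 left out (0.302). Macrophages and dendritic cells did not pass (median 0.29 over 18 genes, range 0.05 to 0.26, adjusted p = 0.138). In that list the scavenger receptor gene Marco was 9.74-fold higher in mLN (3.28 ± 0.15, adjusted p = 0.0108). The mannose receptor gene Mrc1 was 4.13-fold higher (2.05 ± 0.20, adjusted p = 0.0365, but 0.054 with the experiment as a block). The call of Mrc1 also ended with either mLN array left out (values 1.90 and 2.19). The mean scaled log2 signal of Marco was 5.73 in mLN and 2.45 in pLN, against −1.48 and −1.54 for Ptprc. That of Mrc1 was 0.06 and −1.98. The medians of the list lay between −2.45 (pLN replicate 2) and −1.70 (mLN replicate 1). Which cells carried Marco and Mrc1 was not tested, so their values do not show leukocytes left in the preparations. Erythroid genes were lower, with a median of −0.73 over 12 genes, or −0.60 with 1 of them at its bound (range −1.13 to −0.42, adjusted p = 0.00658, and adjusted p = 0.725 with an estimated correlation), but did not pass among probes well above background on all 4 arrays (0.0682). Cell cycle genes were lower, with a median of −0.28 over 25 genes (range −0.63 to 0.00, adjusted p = 0.0189, and adjusted p = 0.778 with an estimated correlation). Their median was 0.00 with mLN replicate 2 left out and −0.21 with pLN replicate 1 left out, and the list did not pass in either case. Immediate early and heat shock genes did not pass (median −0.17 over 23 genes, 0.417), and of the sex-linked list Xist alone was tested (0.29, not called).

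Adjustment over a list alone also passed members of lists for which no such count is given above. In skeletal muscle there were 3 genes higher and 3 lower in mLN, in matrix proteases 2 and 4, in intestinal epithelium 2 and 2, and among inflammatory chemokines and cytokines 4 lower. Follicular dendritic and marginal reticular cells had 4 higher and 1 lower, cholesterol efflux 3 and 1, Schwann cells 2 and 1, plasma cells 3 higher, and collagens and macrophages 2 higher each. A single gene, higher in mLN, passed among T cells, matricellular genes, homeostatic chemokines, lymphatic endothelium and high endothelial venules, and none passed in the remaining lists.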

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

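The normexp backgrounds with 1 value per array and with 11 values replaced, and the count without genes of neighbouring tissues were chosen after the data had been seen, and the other alternatives before. Of the 225 genes called in the reported setting, 225 were called with median scaling, 208 with an intensity trend, 205 with quantile scaling, 199 with the value table, 200 with the mean of a gene's probes, 191 with the block, 181 with normexp on 1 background per array and 154 among probes well above background on all 4 arrays. Median scaling called 354 genes (253 higher and 101 lower in mLN), the intensity trend 441 (322 and 119), and normexp with 1 background per array 358 (267 and 91). Their causes were not tested. Without a filter on dim probes 44 genes were called (37 and 7), with 27586 genes tested and a prior of 1.93 degrees of freedom, and 25 of 39 called named genes did not pass; the cause was not tested. With quantile scaling, the value table, the stricter filter, the mean of probes, each probe and a 2-fold limit, the totals were 239, 276, 210, 214, 234 and 225. Without the genes of neighbouring tissue lists 207 remained, 151 higher and 56 lower.

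The planned normexp background, from local backgrounds, called 0 genes in limma (0 higher and 0 lower, with 569 at an unadjusted p below 0.05). On mLN replicate 2, 11 spots had a local background over 100 above their signal, at the extreme 61899 against a signal of 100, and the fitted background mean was −1288 there against −11.5 to −10.6 on the other arrays. With only those 11 backgrounds replaced by the array median, the fitted mean there was −25.2 and 582 genes were called (434 and 148), 189 of them among the 225, which shows that these spots caused the 0. Why this form called more genes than the reported setting was not tested. It ended the calls of Esrp1 (adjusted p = 0.219), Olfr1046 (0.0556) and erythroid genes (0.0512, median −0.12, against −0.25 with 1 background per array). The rule of 2-fold in both experiments took 555 genes under the planned form, 502 with 1 background per array and 499 with the 11 replaced, where the offset pulls dim signals together by construction, and 669 to 1153 under the other settings. The planned form moved the median of all genes to 0.38 and turned the sign of 30 of the 225 genes called in the reported setting. It turned Ccl19 to −0.22, Pdpn to −0.0642, Crabp2 to 0.87, Esrp1 to 1.17, Olfr1046 to 0.68 and Slc27a2 to 1.16, and relative to that median all 6 were still turned. It turned 9 list medians, B cells to 0.22, Schwann cells 0.73, adipocytes 0.54, erythroid cells 0.99, fatty acid oxidation −0.0534, fibroblastic reticular cells −0.14, homeostatic chemokines −0.18, other regional transcription factors 0.12 and pan-leukocyte 0.26. Relative to the median of all genes, B cells, Schwann cells and other regional transcription factors were not turned and the other 6 were. It ended 10 list calls, for T cells (adjusted p = 0.1), retinoid genes (0.1), cell cycle (0.38), collagens (0.629), cholesterol efflux (0.717), pericytes (0.906), follicular dendritic cells (0.906), complement (0.923), matricellular genes (0.976) and erythroid cells (0.976).

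With the experiment as a block, which keeps the pairing of the experiments, 333 genes were called (248 and 85). Of 84 named genes 5 gained and 4 lost the call, and 1 list gained it (lymphatic endothelium). Each experiment holds 1 array per node, so the block leaves every fold change as it was and could not change a sign. A block for slide or scan was planned and not run, since 1 slide and 1 scan hold all arrays. The number of lists passing was 16 to 23 in the settings with the preset correlation and 0 with the estimated correlation, a form that called no shifted list in the simulations either. The lists behind this number differed between settings. Under the planned normexp background 16 passed although 10 of the reported 17 did not. Fibroblastic reticular cells, not called in the reported setting, passed there with a turned median of −0.14 (camera adjusted p = 0.0293). List medians near 0 turned in other settings and none of these lists passed in the reported one. Pan-leukocyte genes had 0.0321 with normexp on 1 background per array, 0.0458 with 11 backgrounds replaced, 0.0279 with quantile scaling, 0.0032 with median scaling and 0.00123 with the mean of probes. Schwann cells had 0.0281 without a filter and 0.0371 with 11 backgrounds replaced. Skeletal muscle had −0.0146 with normexp on 1 background per array and −0.0226 without a filter. Fatty acid binding had −0.00874 without a filter and −0.00874 with the stricter one. Lipoprotein uptake had −0.016 with normexp on 1 background per array, −0.0159 with the stricter filter and −0.0207 with the mean of probes. The cause was not tested.

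Leaving out an array leaves 1 in its node, which is assumed to vary like the others. Over the 4 arrays left out, limma called 0 to 190 genes in total, 0 to 153 higher and 0 to 52 lower in mLN. The 0 came without pLN replicate 1 and without pLN replicate 2 (1877 and 2297 genes at an unadjusted p below 0.05), and 37 lower genes without mLN replicate 2. Genes whose sign turned in this way had Ccl19 −0.33 to 0.57, Cd36 −0.84 to 0.13, Cxcl13 −0.26 to 0.14, Fabp4 −0.60 to 0.12, Pdpn −0.12 to 0.18, Ptprc −0.17 to 0.28. List medians that turned had Hox genes −0.0465 to 0.0765, Schwann cells and nerve −0.0305 to 0.11, adipocytes −0.51 to 0.32, antigen processing and presentation −0.23 to 0.00933, basement membrane −0.0798 to 0.16, cell cycle −0.63 to 0.00246, fatty acid oxidation −0.0548 to 0.12, fatty acid synthesis and desaturation −0.25 to 0.11, high endothelial venules and peripheral addressin −0.50 to 0.16, homeostatic chemokines and lymphoid survival factors −0.0897 to 0.22, immediate early and heat shock genes −0.60 to 0.26, inflammatory chemokines and cytokines −0.79 to 0.20, intestinal epithelium −0.14 to 0.30, lipid droplets and triglyceride turnover −0.0519 to 0.25, lipoprotein uptake and handling −0.093 to 0.25, pan-leukocyte −0.12 to 0.13. Of 39 called named genes, 11 did not pass without mLN replicate 1 and 9 without mLN replicate 2. Fewer arrays is part of the cause by construction. Without a pLN array the residual spread comes from the mLN arrays alone, so the 0 does not show that the pLN arrays carry the differences. Across genes, experiment 2 minus 1 had an SD of 0.51 in mLN and 0.46 in pLN. Why the numbers called differed between the nodes was not tested further.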

Other observations

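The 3 tests on pancreatic genes were chosen only after the result was seen, the others before. Named genes outside the rule, Csn2, Tcf21, Twist1, Muc16, Krt7 and Cldn15, were chosen after their values were seen.

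Tcf21, a basic helix-loop-helix gene of visceral mesenchyme, was 97.2-fold higher in mLN (log2 fold change 6.60 ± 0.51, limma adjusted p = 0.0214), and Twist1, a mesenchymal factor of the same family, was 12.4-fold lower (−3.63 ± 0.19, adjusted p = 0.0124). Further called mesothelial genes were Muc16 (4.61 ± 0.30, adjusted p = 0.0159), with probes at 0.26 and 4.61, the claudin gene Cldn15 (2.66 ± 0.21, adjusted p = 0.0234) and the keratin gene Krt7 (2.01 ± 0.15, adjusted p = 0.0208). The milk protein gene Csn2 was higher in mLN (4.36 ± 0.14, adjusted p = 0.00697), opposite to Csn3.

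Mesothelial genes stood above pLN in mLN, with Msln at 3.07 on the log2 scale relative to the 75th percentile against −5.80 in pLN, and Upk3b at 3.13 against −6.49. Over 4 other settings (planned normexp background, quantile scaling, median scaling and the value table) the lowest median of the list was 2.47. The value table keeps the 75th percentile as its scale, and median scaling shifts all genes of an array alike, so neither could move the median far. The values with normexp and quantile scaling argue against scaling or background correction as the whole cause. Mesothelial cells in the mLN preparations may contribute: of 9 further mesothelial genes 8 were positive in both experiments, and the lower of the experiments' medians was 1.05, and removal of CD45-positive cells would leave such cells in place. Whether they also carry the Aldh1a2 difference is weakly tested, since its shift of −0.72 between the mLN arrays lay at the edge of the range of called mesothelial genes (−0.72 to −0.17) and within the spread of all genes (SD 0.51). A difference in the stroma of the nodes, which the design names, stays open and was not tested, and 2 of the 15 list members also stood in another list.

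Pancreatic acinar genes stood above pLN in mLN in both experiments, with list medians of 6.56 and 5.12 on the mLN arrays against 1.04 and −5.23 on the pLN arrays. Cross-hybridisation among serine proteases is argued against, since 10 members that are not such proteases had medians of at least 6.07. Mixing of mLN material into the pLN preparation of experiment 1 as the source of the pancreatic signal there is argued against, since it would cap every ratio, and 3 mesothelial genes well above background on that array had ratios more than 1 SD (0.66) above the highest pancreatic ratio of 6.99. Pancreatic RNA carried over in differing amounts is a candidate explanation, as the 17 genes moved together between the mLN arrays by a median of −1.72 (SD 0.35), and CD45 depletion would not remove acinar cells. A difference between the nodes themselves, which the design names, stays open and was not tested.

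Epithelial genes stood below pLN in mLN. Mammary or other luminal epithelium in the pLN preparations could not be told from other sources: the higher of the experiments' medians over 13 such genes was −0.65, 5 of them were at least 2-fold lower in both experiments, and 3 were higher in both, Csn2 among them. Skin keratinocytes could not be told either, since 10 such genes went both ways and the higher of the experiments' medians was −0.034 (−0.26 for the fold changes). CD45 depletion would leave either cell type in place. A difference between the nodes themselves may also account for these values and was not tested.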
